A study of Mus musculus with 6 samples.

How the data were processed

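Kidney RNA from 6 male mice aged 10 weeks was measured, per the labels, on 1 Affymetrix oligonucleotide array per animal. In 3 mice the soluble intracellular domain of megalin was expressed (ICD group), and 3 littermates served as wild type controls. Groups and replicate numbers were taken from the labels.

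The deposited values are on a log2 scale, as their range of 3.11 to 15.11 shows, and RMA is the method named in the submitters' processing notes. RMA corrects the background, forces all arrays to 1 distribution (quantile normalization) and summarises the probes of a probe set by median polish, so that a shift shared by most transcripts of an array would be removed and differences of dim probe sets are compressed. The version of RMA, the chip definition and any filter were not given in the sources used here. Medians of the 6 arrays lay between 6.62 and 6.66, and correlations between pairs of arrays lay between 0.9949 and 0.9966. No pair of arrays held identical values. Every value column belonged to 1 labelled sample. The scanner files were not used here.

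The table held 45101 rows. The 64 control rows were left out of the comparison, which leaves 45037 probe sets. The platform annotation gave 1 gene symbol for 34945 of these, several for 932 and none for 9160. Probe sets without a listed gene are called unnamed here, and no gene was named from a probe set with several symbols. Symbols were checked through Entrez identifiers in the RefSeq table of assembly GRCm38.p6, in which 34741 of the probe sets with 1 gene were found and 0 symbols had to be updated. That table was used only for names and for which genes neighbour each other.

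ICD and wild type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, genotype as the only term, 2-sided), with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of adjusted p under 0.05. Differences are ICD minus wild type on the log2 scale, with a standard error or a 95% confidence interval from the same fit. In the closing section, intervals of medians over genes or probe sets come from 2000 bootstrap draws of those genes or probe sets. They do not measure the variation between animals. An exact permutation test of 3 against 3 animals cannot give a 2-sided p below 0.1, so none was used for single genes. The median interval reached 0.19 to either side of the estimate, over all probe sets and over the brighter part alone.

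In simulated data, 200 of 45037 probe sets were changed in each of 5 runs. The noise was normal, with spreads drawn at random from limma's fitted prior and not taken from each probe set. Limma recovered 41.8% of changes of 0.5, 93.7% of changes of 1 and 100% of changes of 2 on the log2 scale. It called 39 of 224185 unchanged ones. In the real arrays 7 of 18 probe sets with a difference of 1 or more had an unadjusted limma p under 0.05. The simulated rates therefore do not carry over to each real probe set. A simulated shift of 0.3 in the podocyte list was called in 20 of 20 runs, with 3 calls among 660 tests of other lists. The simulated genes varied independently of each other. In the real arrays the estimated correlation between genes of a list had a median of 0.115 over the lists, and was 0.295 for podocytes. The simulation therefore gives no rate of false calls for the real lists.

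Before the data were examined, 20 functional gene lists and 14 lists of cell type markers were fixed, along with the tests, the rule for named genes and all but 1 of the alternatives. Each list was tested with limma's camera (preset correlation between genes of 0.01, 2-sided, adjusted over the 34 lists), with 1 probe set per gene, the one with the highest mean over all 6 arrays, for 18194 genes. The functional lists were receptor and adaptors, endocytosis and lysosome, gamma-secretase and sheddases, the LDL receptor family, sodium and phosphate reabsorption, vitamin handling, solute transporters of the proximal tubule, proximal tubule metabolism, fatty acid oxidation and PPAR alpha targets, cholesterol and lipid synthesis, tubular injury, matrix and fibrosis, interferon response, immediate early genes, heat shock and unfolded protein response, circadian clock, Notch targets, Hedgehog and Wnt, neighbours of Lrp2, and androgen dependent kidney genes. The cell type lists covered podocytes, the tubule segments, endothelium, stroma and smooth muscle, myeloid and lymphoid cells, blood, adipose tissue, adrenal gland and urothelium. A list score is the mean, over members, of the log2 value minus the mean of the 6 arrays.

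Named genes followed a fixed rule: every Lrp2 and Slc9a3 probe set; every probe set past the threshold if 20 or fewer passed; in that case also, as a ranking, the 8 largest positive and 8 largest negative differences among probe sets with 1 gene, a mean at or above the median of all probe sets, unadjusted p under 0.01 and no overlap between the groups; Cubn, Dab2, Lrpap1, Clcn5, Slc34a1, Cyp27b1, Cyp24a1, Pth1r, Havcr1 and Lcn2; the 3 members with the smallest p in each called list, along with members past the threshold; and the 3 neighbours of Lrp2 with the smallest p. Eif2s3y was named as a check of sex. The podocyte genes Ptpro, Podxl and Nphs1, as well as Lrp12, Ugt2a3 and the unnamed probe sets, fell outside the rule and were chosen after their values were seen, as were the genes named for their variation between animals.

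Alternatives were a further quantile normalization, median centring, the brighter part of the probe sets only, the replicate number as a block, a trended and robust variance prior, array weights, leaving out each array, other thresholds, 1 probe set per gene, no probe sets of the x and s type, which can match several transcripts, the mean of all probe sets of a gene, and, for lists, camera with an estimated correlation and fry. Camera with an estimated correlation and without the array labelled wild type 3 was added after seeing the data.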

Results

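Megalin, encoded by Lrp2, is the large endocytic receptor of the proximal tubule, and cleavage of its tail releases a soluble intracellular domain (ICD). The series asked whether this domain, expressed in the mouse, changes proximal tubular function, and the arrays ask which kidney transcripts differ between 3 ICD mice and 3 wild type littermates. All 6 animals were male and 10 weeks old. The Y-linked transcript Eif2s3y lay between 8.93 and 9.21 (log2) on every array. The replicates are separate animals.

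Megalin's own transcript was measured by 3 probe sets, of which none passed the test. The bright probe set 1427133_s_at read 12.29 ± 0.064 (SD, n = 3) in ICD kidneys and 12.70 ± 0.50 in wild type kidneys, a difference of -0.41 (95% confidence interval -0.89 to 0.068, limma adjusted p = 0.891). The wild type spread came from 1 array: the arrays labelled wild type 1 and 2 read 13.01 and 12.97, whereas the array labelled wild type 3 read 12.13, below all 3 ICD arrays (12.25, 12.37 and 12.26). Without it the difference was -0.70 (interval -0.88 to -0.52), still at a limma adjusted p of 0.186, whereas without wild type 1 or 2 it was -0.26 or -0.28. The other bright probe set, 1452320_at, read 12.83 ± 0.087 in ICD and 12.83 ± 0.081 in wild type kidneys, a difference of 0.0079 (interval -0.17 to 0.18). The dim probe set 1445901_at differed by 0.12 (interval -0.25 to 0.49). The labels do not say which part of Lrp2 the introduced allele carries, so these probe sets check the genotype labels only in part, and the array labelled wild type 3 is named as such throughout.

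Slc9a3 encodes the sodium/proton exchanger NHE3 of the apical membrane, the transcript most often discussed as a target of the megalin domain. Its bright probe set 1441236_at read 10.24 ± 0.027 (SD, n = 3) in ICD and 10.14 ± 0.13 in wild type kidneys. The difference of 0.11 had an interval of -0.078 to 0.29 (limma adjusted p = 0.948). The dimmer 1432771_at differed by 0.29 (interval -0.060 to 0.63, adjusted p = 0.899). Neither probe set passed the test. Without wild type 1 the difference at 1441236_at was 0.033, and without wild type 2 it was 0.16. At 1432771_at it was 0.13 without ICD 1 and 0.18 without the array labelled wild type 3.

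**Figure D1:**
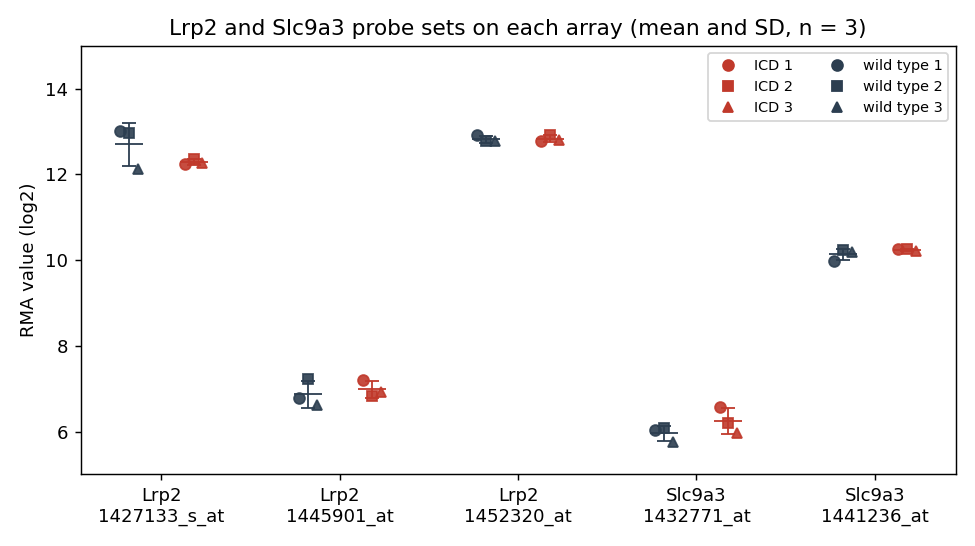
RMA values (log2) of the 3 Lrp2 and 2 Slc9a3 probe sets on each array, with ICD animals in red and wild type animals in dark blue, marker shapes for replicate numbers, and bars for the mean and SD of 3 animals. At 1427133_s_at the array labelled wild type 3 (12.13) lies with the ICD arrays, and at 1452320_at both groups average 12.83.

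Megalin's partners and genes of phosphate and vitamin D handling did not pass the test. Cubn, the co-receptor cubilin, differed by 0.070 (interval -0.081 to 0.22), Dab2, an endocytic adaptor, by 0.092 (interval -0.13 to 0.32), and Lrpap1, the receptor's chaperone, by -0.024 (interval -0.17 to 0.12). Clcn5, the endosomal chloride/proton exchanger, differed by 0.047 (interval -0.16 to 0.25). Slc34a1, the main phosphate transporter of the brush border, differed by 0.088 (interval -0.10 to 0.28), and Pth1r, the parathyroid hormone receptor, by 0.017 (interval -0.15 to 0.19). Intervals were wide for the vitamin D enzymes: Cyp27b1, which makes the active hormone, differed by 0.36 (interval -0.34 to 1.06), and Cyp24a1, which degrades it, by 0.83 (interval -0.89 to 2.54). The difference of Cyp27b1 was 0.057 without ICD 2, 0.16 without the array labelled wild type 3 and 0.67 without wild type 1. Without the array labelled wild type 3, Dab2 differed by 0.0013 and Slc34a1 by 0.011. Cyp24a1 read 6.91 on the array labelled wild type 3 and 9.99 and 9.27 on the other wild type arrays. Its difference was -0.082 without the array labelled wild type 3 and 1.46 without wild type 1. The sign also turned without some single array for Clcn5, Pth1r, Havcr1 and Lcn2. The injury markers Havcr1 and Lcn2 differed by 0.031 (interval -0.16 to 0.22) and 0.082 (interval -0.36 to 0.52). Adjusted p lay above 0.95 for each of these genes.

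Across the kidney transcriptome, 0 of 45037 probe sets passed limma's threshold. At unadjusted p under 0.05 there were 2641 probe sets, 1624 higher and 1017 lower in ICD kidneys, where 2252 are expected by chance. Among control probe sets, 18S ribosomal RNA averaged 7.58 ± 0.32 (SD) in ICD and 7.21 ± 0.14 in wild type arrays, and the bacterial poly-A spikes 7.85 ± 0.10 and 8.01 ± 0.13, with overlap between the groups for both. The smallest adjusted p, 0.102, belonged to the unnamed probe set 1447096_at, chosen after its values were seen, which read 8.50 ± 0.099 (SD, n = 3) in ICD and 7.51 ± 0.12 in wild type kidneys. The groups did not overlap for 10.5% of probe sets, and chance gives 10% for 3 against 3. Differences of 1 or more on the log2 scale were measured for 18 probe sets, of which 7 had an unadjusted p under 0.05. In limma fits without 1 array, 1 probe set each passed: Ugt2a3, a glucuronosyltransferase (difference 1.60, adjusted p = 0.0148), without ICD 1, the unnamed 1435872_at (1.81, adjusted p = 0.036) without ICD 2, and the unnamed 1448754_at (-2.28, adjusted p = 0.0113) without the array labelled wild type 3. With a trended and robust prior, 1447096_at passed at adjusted p = 0.0301.

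The fixed rule ranks the largest differences without calling them changed. The highest differences belonged to Mtss1, a membrane-bending protein (0.94 ± 0.21 SE), Pik3c2g, a lipid kinase (0.78 ± 0.089), Slc7a13, an amino acid transporter of the late proximal tubule (0.76 ± 0.20), Hspa8, a constitutive chaperone (0.68 ± 0.16), and Emp1, an epithelial membrane protein (0.63 ± 0.081). Cit (0.61), 3110045C21Rik (0.60) and Tlk2 (0.59) followed. The lowest belonged to Apoh, an apolipoprotein (-0.83 ± 0.13 SE), Rgs5, a regulator of G protein signalling in pericytes (-0.66 ± 0.079), Coq8a, needed for coenzyme Q synthesis (-0.64 ± 0.12), 9030619P08Rik (-0.61), Arntl, a core clock factor (-0.53 ± 0.15), Uap1 (-0.50), Pnpla3 (-0.50) and H2aj (-0.50). Adjusted p in limma lay between 0.269 and 0.714. Of the 12 ranked genes with a further probe set, 6 had at least 1 of opposite sign: the other Rgs5 probe sets differed by 0.18 to 0.52, that of Apoh by 0.084, and those of Hspa8 by -0.14 to -0.046. The other Tlk2 probe sets differed by -0.18 to -0.046. All 6 Mtss1 probe sets were higher in ICD kidneys, but the brightest by 0.079. Same-sign probe sets were often near 0: the brighter one of Slc7a13 differed by 0.069, and the others of Emp1 by 0.055, Arntl by -0.016 and H2aj by -0.10 to -0.086. That of Coq8a differed by -0.34.

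**Figure D2:**
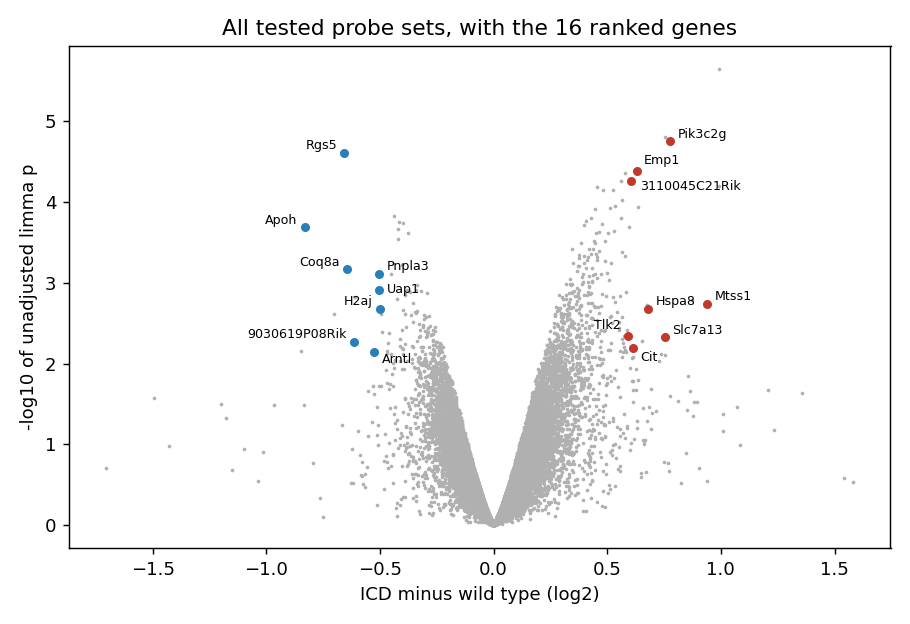
Difference between ICD and wild type kidneys (log2) against the -log10 of the unadjusted limma p for each of 45037 probe sets (grey). The ranked genes are coloured, 8 higher in red and 8 lower in blue, and none reached the threshold (smallest adjusted p among them 0.269).

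Of the 34 lists, the podocyte markers had the smallest p. All 10 measured podocyte markers were higher in ICD kidneys, by a median of 0.30 on the log2 scale (limma camera adjusted p = 7.16e-10). With an estimated correlation the adjusted p was 0.592. No member passed over all probe sets, and 6 passed adjusted over the list alone: Cdkn1c, a cell cycle inhibitor (0.55 ± 0.13 SE), Wt1, the podocyte transcription factor (0.52 ± 0.13), Ptpro (0.51 ± 0.14), Podxl, the anionic coat protein (0.41 ± 0.11), Synpo, an actin-binding protein of foot processes (0.35 ± 0.095), and Nphs1, the slit diaphragm protein nephrin (0.25 ± 0.080). That adjustment was made within each list and not across the 34 lists, so a pass in some list is expected by chance. Podocyte scores were 0.068, 0.21 and 0.17 in ICD arrays and -0.016, -0.23 and -0.20 in wild type arrays. The list was called without any 1 array (medians 0.26 to 0.47, the highest without wild type 1; highest adjusted p 1.15e-06). Of the 10 splits of the 6 arrays into 3 and 3, 3 that mixed the genotypes called it too (camera adjusted p = 1.26e-05, 0.0036 and 0.0147).

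Markers of segments that reach the medulla lay lower. Among principal cell markers 11 of 13 were lower (median -0.051, camera adjusted p = 0.0117, and adjusted p = 0.592 with an estimated correlation), led by Avpr2, the vasopressin receptor (-0.23 ± 0.066 SE), Scnn1a, a subunit of the epithelial sodium channel (-0.21 ± 0.070), and Elf5 (-0.28 ± 0.11, and -0.18 without wild type 1). Among markers of the thick ascending limb 9 of 11 were lower (median -0.082, camera adjusted p = 0.0356, and adjusted p = 0.698 with an estimated correlation). Of these Ptger3, a prostaglandin receptor, passed adjusted over the list alone (-0.35 ± 0.079), with a limma adjusted p of 0.6 over all probe sets. Kcnj1 and Slc12a1, the potassium channel and the sodium-potassium-chloride cotransporter of the segment, differed by -0.15 and -0.097 (-0.093 without the array labelled wild type 3 and -0.056 without ICD 3). Urothelial markers were lower for 10 of 11 (median -0.11, camera adjusted p = 0.0125, and adjusted p = 0.592 with an estimated correlation), with Psca (-0.21 ± 0.064), Sprr1a (-0.22 ± 0.093) and Krt15 (-0.21 ± 0.092). Endothelial markers were higher for 14 of 15 (median 0.086, camera adjusted p = 0.0472, and adjusted p = 0.738 with an estimated correlation), with Egfl7 at 0.25, Ptprb at 0.12 and Cdh5 at 0.12. Their score was highest on wild type 1 (0.23), above all 3 ICD arrays (-0.038, 0.0078 and 0.15). The estimated correlation of 0.76 means that these markers largely moved as 1. Without the array labelled wild type 3 Egfl7 and Ptprb differed by 0.079 and 0.041, and without wild type 2 Cdh5 differed by 0.051. Adipose markers were higher for 8 of 11 (median 0.17, camera adjusted p = 0.0356, and adjusted p = 0.699 with an estimated correlation), with Retn at 0.37, Car3 at 0.35 and Adipoq at 0.43 (0.18, 0.18 and 0.15 without wild type 1). Each of these calls was lost without at least 1 array: principal cells without ICD 3 or the array labelled wild type 3 (adjusted p up to 0.264), the thick limb and endothelium without ICD 3, wild type 2 or the array labelled wild type 3 (up to 0.353 and 0.691), urothelium without ICD 2 or wild type 1 (up to 0.091), and adipose tissue without ICD 1, ICD 2 or wild type 1 (up to 0.937). The principal cell median was -0.12 without ICD 2, -0.088 to -0.090 without ICD 1, wild type 1 or wild type 2, and -0.030 without the array labelled wild type 3. The urothelial median was -0.050 without wild type 1 and -0.070 without ICD 3. The endothelial median was -0.046 without the array labelled wild type 3, 0.020 without ICD 3 and 0.22 without wild type 1. The adipose median was 0.028 without wild type 1, 0.10 without ICD 1, 0.26 without the array labelled wild type 3, 0.28 without ICD 3 and 0.29 without wild type 2; without wild type 1 its mean was -0.046, of opposite sign to the median. The endothelial call was also lost after quantile normalization (adjusted p = 0.0609), among bright probe sets alone (0.0829) and with the mean of all probe sets of a gene (0.0941), and the adipose call among bright probe sets (0.0772).

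**Figure D3:**
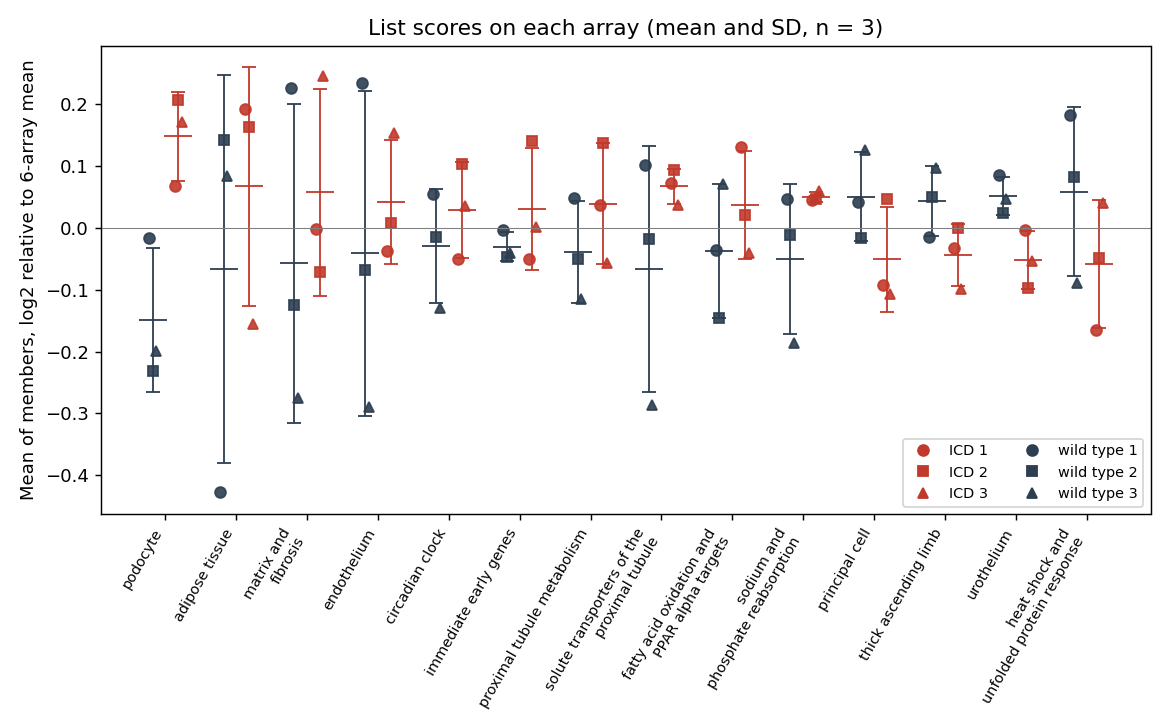
Mean score of each called list on each array (log2, relative to the mean of the 6 arrays), with ICD animals in red, wild type animals in dark blue, and bars for the mean and SD of 3 animals. Podocyte scores of all 3 ICD arrays (0.068 to 0.21) lie above those of all 3 wild type arrays (-0.23 to -0.016), whereas for endothelium and matrix the array labelled wild type 3 is the lowest (-0.29 and -0.28). The endothelial score of wild type 1 (0.23) lies above those of all 3 ICD arrays.

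Proximal tubule genes were shifted up as lists by small medians. Sodium and phosphate genes were higher for 12 of 16 (median 0.024, camera adjusted p = 0.0472, and adjusted p = 0.592 with an estimated correlation), solute transporters for 25 of 37 (median 0.031, camera adjusted p = 0.0117, and adjusted p = 0.698 with an estimated correlation), and metabolic enzymes for 19 of 30 (median 0.037, camera adjusted p = 0.0293, and adjusted p = 0.592 with an estimated correlation). The array labelled wild type 3 read 6.46 for Slc34a3, a phosphate transporter, where the other arrays read 8.68 to 9.35, and 9.43 for Slc6a19, a transporter of neutral amino acids, where the others read 10.63 to 11.15. It also read 10.40 for Slc5a2, the glucose transporter SGLT2, where the others read 11.29 to 11.96. Group differences were 1.09 ± 0.59 (SE), 0.81 ± 0.31 and 0.61 ± 0.32 for these genes, and 0.25, 0.38 and 0.20 without that array. Smaller differences were measured for Slc4a4, the basolateral bicarbonate transporter (0.21 ± 0.089), Car4 (-0.13), Slc2a2 (0.24), Miox (0.19), Mme (0.20) and Pck1 (0.17). Of these Slc2a2 and Miox differed by 0.081 and 0.077 without the array labelled wild type 3, Mme by 0.080 without wild type 1 and Pck1 by 0.081 without wild type 2. The marker list of the segment was not called (10 of 15 higher, median 0.041, camera adjusted p = 0.0569), and its score was -0.50 on that array and 0.034 to 0.19 on the others. The mean differences of the called lists were 0.10, 0.14 and 0.078 with all arrays and 0.032, 0.025 and 0.040 without that array. The medians without it were 0.028, 0.033 and 0.032, and the adjusted p was 0.368, 0.155 and 0.213. For solute transporters the score of wild type 1 (0.10) lay above those of all 3 ICD arrays (0.037 to 0.093). Without ICD 2 the mean of the metabolic list was 0.029. Calls were also lost without wild type 2 or ICD 2 for all 3 lists, and without ICD 1 or ICD 3 for sodium and phosphate genes (adjusted p up to 0.233, 0.091 and 0.27 in these fits). The sodium and phosphate median was 0.056 without ICD 1 and 0.045 without wild type 1. The solute transporter median was 0.013 without ICD 2, 0.067 without ICD 3 and 0.076 without wild type 1, and the metabolic median 0.012 without ICD 2, 0.058 without ICD 3 and 0.021 with array weights. Among bright probe sets alone the sodium and phosphate call (adjusted p = 0.0683) and the metabolic call (0.0519) were lost, the former also with the mean of all probe sets of a gene (0.0941).

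Among the other functional lists, chaperones and genes of the unfolded protein response were lower for 25 of 31 (median -0.12, camera adjusted p = 0.0104, and adjusted p = 0.698 with an estimated correlation). Asns, the amino acid response enzyme asparagine synthetase, differed by -0.46 ± 0.16 (SE) and Sel1l, a factor of endoplasmic reticulum degradation, by -0.21 ± 0.069, whereas the heat shock gene Dnajb1 differed by 0.38 ± 0.10. Fatty acid oxidation genes were higher for 18 of 27 (median 0.030, camera adjusted p = 0.0498, and adjusted p = 0.699 with an estimated correlation), with Ppara (0.50 ± 0.17) and its coactivator Ppargc1a (0.41 ± 0.14) at the top and Pdk4 at 0.33 (0.19 without the array labelled wild type 3). Matrix genes were higher for 22 of 25 (median 0.12, camera adjusted p = 0.00372, and adjusted p = 0.699 with an estimated correlation), with Ccn2 at 0.23, Mmp2 at 0.18 and Col4a2 at 0.14. The matrix score was 0.23 on wild type 1 and -0.0025, -0.072 and 0.25 on the ICD arrays, at an estimated correlation of 0.65 between members. Without the array labelled wild type 3 Ccn2 and Col4a2 differed by 0.13 and 0.082, and without ICD 3 Mmp2 differed by 0.096. Immediate early genes, which respond within minutes to stimuli or handling, were higher for 19 of 30 (median 0.043, camera adjusted p = 0.0181, and adjusted p = 0.592 with an estimated correlation), with Rgs2 at 0.23, Dusp6 at 0.28 and Ier5 at 0.24. Clock genes were higher for 18 of 26 (median 0.051, camera adjusted p = 0.0472, and adjusted p = 0.698 with an estimated correlation), with Per3 at 0.29 (0.19 without the array labelled wild type 3) and Tef at 0.24 against Arntl at -0.53. Calls were lost without ICD 1, wild type 1 or wild type 2 for chaperones and for fatty acid oxidation (adjusted p up to 0.274 and 0.916), and without ICD 3, wild type 2 or the array labelled wild type 3 for matrix, immediate early and clock genes (up to 0.648, 0.0827 and 0.475). Without ICD 2 the immediate early and clock calls were lost too (adjusted p = 0.259 and 0.316). The fatty acid oxidation median was -0.037 without ICD 1, -0.012 without wild type 2, 0.0037 without wild type 1, 0.079 without the array labelled wild type 3 and 0.083 without ICD 3. The matrix median was 0.034 without ICD 3, 0.035 without the array labelled wild type 3, 0.20 without ICD 2 and 0.25 without wild type 1, and its mean was 0.11 with all arrays and 0.0054 without the array labelled wild type 3. The chaperone median was -0.060 without wild type 1, -0.19 without ICD 3 and -0.20 without the array labelled wild type 3. The immediate early median was 0.0045 without ICD 2, 0.021 without wild type 2 or the array labelled wild type 3, 0.075 without wild type 1 and 0.079 without ICD 1. It was 0.013 with array weights and 0.066 among bright probe sets. The clock median was 0.030 without ICD 2, 0.033 without the array labelled wild type 3, 0.086 without ICD 3, 0.12 without wild type 1 and 0.13 without ICD 1. The fatty acid oxidation call was also lost after quantile normalization (adjusted p = 0.058), among bright probe sets (0.0923) and with the mean of all probe sets of a gene (0.448). With that mean the immediate early call was lost too (median 0.017, adjusted p = 0.0941), and array weights ended the clock call (median 0.018, adjusted p = 0.109).

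The lists nearest to megalin were not called. Receptor and adaptor genes had a median of 0.021 (9 of 13 higher, camera adjusted p = 0.488), endocytosis and lysosome genes 0.0055 (19 of 34 higher, adjusted p = 0.541), gamma-secretase and sheddase genes 0.023 (7 of 10 higher, adjusted p = 0.563) and vitamin handling genes -0.0065 (7 of 15 higher, adjusted p = 0.563). In the LDL receptor family (6 of 13 higher, adjusted p = 0.511) Lrp12 passed adjusted over the list alone (-0.42 ± 0.092 SE), but not over all probe sets. Over all lists 8 members passed in this way, without adjustment across the 34 lists, and 0 passed over all probe sets. The neighbours of Lrp2 had a median of 0.017 (23 of 40 higher, adjusted p = 0.679), and those with the smallest p were Scn2a (-0.19 ± 0.089), Stk39 (-0.16 ± 0.078) and Gorasp2 (-0.098 ± 0.072, and -0.057 without ICD 1). Tubular injury genes had a median of -0.059 (8 of 26 higher, adjusted p = 0.185), and cholesterol synthesis (0.012, adjusted p = 0.889), interferon response (-0.014, adjusted p = 0.163), Notch (0.0028, adjusted p = 0.425), Hedgehog and Wnt (-0.025, adjusted p = 0.835) and androgen dependent genes (-0.019, adjusted p = 0.713) lay near 0.

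The remaining cell type lists were not called either. Medians were -0.023 for the distal convoluted and connecting tubule (camera adjusted p = 0.565), -0.022 for intercalated cells (0.563), 0.027 for stroma and smooth muscle (0.214), 0.044 for macrophages and myeloid cells (0.618), 0.035 for antigen presentation and lymphocytes (0.179), -0.031 for blood (0.185) and -0.021 for adrenal gland (0.252). The direction of the camera test and the sign of the median differed for 5 lists (vitamin handling, interferon response, Hedgehog and Wnt, androgen dependent genes, and the distal convoluted and connecting tubule), and mean and median differed in sign for 4 (vitamin handling, interferon response, androgen dependent genes and neighbours of Lrp2). None of the 34 lists passed with an estimated correlation (smallest adjusted p = 0.592). None passed with fry either, which asks whether the genes of a list move on balance in 1 direction (smallest adjusted p = 0.451). With an estimated correlation 1 list had an unadjusted camera p under 0.05. The adjusted p also rose to 0.592 where the estimated correlation was low, from 0.0472 for sodium and phosphate genes (correlation 0.0285). It rose likewise from 0.0181 for immediate early genes (0.0327) and from 0.0293 for metabolic enzymes (0.0397). This setting therefore does not tell whether correlation between genes alone ended these calls.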

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

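The 64 control probe sets were left out of the comparison, and 5 of them read higher on all 3 ICD arrays than on all 3 wild type arrays, where 3.2 are expected by chance in each direction. A further 4 read lower on all ICD arrays: the poly-A spikes lys (3' end, -0.21), phe (3' end, -0.12) and thr (middle, -0.15), and the control TrpnX (middle, -0.22). All 24 probe sets of the poly-A spikes, which are not independent of each other, had a lower mean in ICD arrays, by -0.15 on average, but their averages per array overlapped between the groups. Of the 5, those at the 3' end of pyruvate carboxylase and at its 2 middle regions differed by 0.097, 0.17 and 0.19 (log2), and the hybridization controls bioB (5' end) and bioD (3' end) by 0.079 and 0.067.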

How the results depend on the processing

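The fit with both an estimated correlation and without the array labelled wild type 3 was chosen after seeing the data. It called 0 lists, with the limit stated above for the estimated correlation. The count of 0 probe sets past adjusted p under 0.05 held after quantile normalization, median centring, array weights, the block, the bright filter, 1 probe set per gene and without x and s probe sets. It was 1 with a trended and robust prior (1447096_at) and 0 to 1 without 1 array each. Other thresholds gave 2641 (unadjusted p under 0.05), 81 (under 0.001) and 59 (under 0.05 and 1.5-fold). Of the 81, 68 were higher and 13 lower in ICD kidneys, where 45 in all are expected by chance. At unadjusted p under 0.05 the bright filter, which tests fewer probe sets, left 1454. The share higher in ICD kidneys was 61.5% of the 2641 and 70.8% of the 1454, and over all probe sets 54.9% after median centring and 59.8% after quantile normalization.

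The replicate number as a block gave 0 probe sets (smallest adjusted p 0.644) and 9 lists in place of 14. Same-numbered animals did not deviate together (r of -0.0057, 0.0077 and -0.047), and no array correlated best with its own number. The block ended the calls for sodium and phosphate, the thick limb and adipose tissue (adjusted p = 0.0509 each), endothelium (0.0608) and the clock (0.076). Lists called were 12 after quantile normalization, 14 after median centring, 10 among bright probe sets (9 of them among the 14), 15 with a trended prior, 14 with array weights (13 of them among the 14), 11 with the mean of all probe sets of a gene, 0 with an estimated correlation, 0 with fry, 0 with fry in either direction, and 4 to 14 without 1 array each (4 without wild type 2, 5 without the array labelled wild type 3, 7 without ICD 3). The podocyte list was called in all 12 of these settings that kept camera's preset correlation and 1 probe set per gene, and also in 3 splits of the arrays that mixed the genotypes.

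Without 1 array each, Lrp2 1452320_at ranged from -0.042 to 0.054 and 1445901_at from -0.011 to 0.30. Array weights gave -0.011 for 1452320_at. Ranges crossed 0 also for Clcn5 (-0.039 to 0.11), Cyp24a1 (-0.082 to 1.46), Pth1r (-0.017 to 0.061), Havcr1 (-0.034 to 0.077) and Lcn2 (-0.12 to 0.21), and the medians of the lists for fatty acid oxidation (-0.037 to 0.083) and endothelium (-0.046 to 0.22). Ranges were wide without a change of sign for Lrp2 1427133_s_at (-0.70 to -0.26), Slc9a3 1441236_at (0.033 to 0.16) and 1432771_at (0.13 to 0.42), Cubn (0.040 to 0.10), Dab2 (0.0013 to 0.15), Lrpap1 (-0.034 to -0.0057), Slc34a1 (0.011 to 0.13) and Cyp27b1 (0.057 to 0.67). The cause was not tested for any of these.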

Other observations

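The tests of the whole Lrp2 transcript, of the proximal tubule share, of RNA degradation, and the splits for probe set counts and for the podocyte list were chosen after the result each measures had been seen.

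Among the 500 genes that varied most between the 6 animals, the groups did not overlap for 36 (7.2%), where chance gives 50. Of genes chosen after their values were seen, Ndrg2 read 7.26, 10.38 and 7.15 in the ICD animals and 9.04, 7.06 and 9.65 in the wild type animals, and its near neighbour Rpgrip1 ran the opposite way (10.66, 6.51 and 10.58 against 9.68, 10.67 and 9.69). Nucb2, which encodes the secreted calcium-binding protein nucleobindin 2, read 6.93, 8.06 and 8.62 in ICD and 7.30, 7.14 and 8.52 in wild type animals. One hypothesis is that stretches of different mouse strains segregate between these littermates. Among the same 500 genes, 28 pairs at most 5 positions apart (order of assembly GRCm38.p6) correlated over the 6 arrays with an absolute r over 0.9, of 155 such neighbours, and 1000 shuffles of the positions gave at most 10. Some pairs are gene families whose members are similar or regulated together (Hspa1a and Hspa1b, C1qa and C1qc, Serpina1c and Serpina1f), for which the shuffles make no allowance, so the excess may come only in part from strain stretches.

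The low Lrp2 probe set on the array labelled wild type 3 was the first pattern weighed. A lower level of the whole transcript is argued against, since without that array 1452320_at differed by -0.017 (interval -0.22 to 0.19) and 1427133_s_at by -0.70. A mislabelled array stays open. Over 58 bright probe sets that part the ICD arrays from the other wild type arrays, the median position of this array was 0.322 (0 for wild type, 1 for ICD). The bootstrap interval over probe sets was 0.17 to 0.51. The positions of wild type 1 and 2, tested likewise, were 0.57 and 0.21. The probe sets were picked for parting the remaining arrays. That alone moves a rightly labelled left-out array away from 0, so the position cannot decide. A stretch of another strain around Lrp2 stays open too, as 0 of 209 probe sets of the 100 nearest genes and 162 of 34529 elsewhere had the same pattern (odds ratio 0, interval up to 3.82, Fisher's exact p = 1). The genotype as the source of the lower values in the ICD arrays was not tested apart from these.

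The higher podocyte markers may come from a larger share of cortex in the ICD tissue pieces, but lists of cortical segments were mixed. Proximal tubule markers were higher for 10 of 15 (camera adjusted p = 0.0569), yet their score was highest on wild type 1 (0.19). Markers of the distal convoluted and connecting tubule were higher for 4 of 9 (median -0.023). Of 10 medulla markers fixed after the podocyte result, 7 were measured and 6 were lower in ICD kidneys. The lower ones were Mal, Cldn4, Slc14a2, Cryab, Slc5a3 and Slc6a12, and Slc6a6 was higher. The median of the 7 was -0.099 (bootstrap interval over genes -0.16 to -0.058). None passed the test (limma adjusted p 0.854 to 0.984), and Slc6a12 was dim (5.72 to 5.98, where the median of all probe sets was 6.64). Medulla scores overlapped between the groups (-0.035 on wild type 1 and -0.0018 on ICD 2). None of the medulla markers was in another list. The lower principal cell and thick limb markers had been seen before this set was fixed, so the test is not fully independent. Podocyte and medulla scores, the only such relation computed, ran opposite over the 6 arrays. Pearson r was -0.77 (exact permutation p = 0.0861) and Spearman rho -0.54 (exact permutation p = 0.297). The groups differ in both scores, so this relation partly repeats the group difference. Over the ICD arrays both scores rose together (podocyte 0.068, 0.17 and 0.21, medulla -0.082, -0.055 and -0.0018). Among wild type arrays the highest podocyte score went with the lowest medulla score (wild type 1). Without the 2 arrays farthest from the median podocyte score, wild type 2 and the array labelled wild type 3, r was 0.39, so the opposite run rests on those. This leaves only wild type 1 beside the ICD arrays, and the narrower range of scores weakens r by itself. A lower share of proximal tubule cells as the only cause would raise markers of other cell types too. Instead, 30 of 35 principal cell, thick limb and urothelial markers were lower (median -0.082, bootstrap interval over genes -0.12 to -0.031). These lists had already been called lower in the same data, and less medulla would lower them as well. The test therefore cannot exclude a lower proximal tubule share beside a change in medulla. An effect of the ICD on podocytes was not tested apart from sampling.

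Unnamed probe sets leaned upward: at unadjusted p under 0.05, 654 were higher and 191 lower in ICD kidneys (77.4% higher), against 970 and 826 (54.0% higher) for probe sets with a listed gene. Scaling that further normalization would remove is argued against, since the gap of 23.4 percentage points was 25.5 after median centring and 27.1 after quantile normalization. RMA already includes a quantile normalization, so these steps could change little. A scaling effect that survives RMA stays open. RNA degradation that shortens transcripts from the 5' end is argued against too. The 3' minus 5' difference differed by -0.0051 (log2) for actin, -0.021 for pyruvate carboxylase and -0.026 for Gapdh. Other signs of RNA composition did differ on average, by 0.36 for 18S ribosomal RNA and -0.15 for poly-A spikes (ICD minus wild type), and their part in the lean was not tested. More nuclear or unspliced RNA in the ICD samples could not be decided. Of 19 probe sets of 5 nuclear-retained RNAs, 15 were higher, with a median of 0.097 (bootstrap interval over probe sets 0.018 to 0.25). Differences were 0.097 to 0.58 for the 7 Malat1 probe sets (smallest limma adjusted p = 0.614) and -0.14 to 0.25 for the other 12. The 6 arrays make 10 splits, too few for a share under 0.05: 2 of them, the real one included, had a gap as large as 23.4, and the highest other gap was 28.5.

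The same limit of 10 splits holds for the other results. For the podocyte list, 1 split, the real one, had a camera adjusted p as small as 7.16e-10, the smallest other was 1.26e-05 (ICD 1 with wild type 2 and 3, absolute median 0.26), and 4 splits, the real one included, called it. For lists, 2 of 10 splits, the real one included, gave as many as the 14 of the real split, and the highest other gave 15. For probe sets at unadjusted p under 0.05, 2 of 10 gave as many as 2641 (highest other 2803). For probe sets past adjusted p under 0.05, the real count was 0, which all 10 reach by construction, so this count decides nothing. The highest others were 8 and 5.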
